A study of Mus musculus with 92 samples.

How the data were processed

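Single cells were sorted from the bone marrow of C57BL/6 mice homozygous for Gfi1-R412X, a premature stop in the gene for GFI1. GFI1 is a zinc finger repressor of transcription that acts in granulocyte development. Per the labels' protocols, marrow from crushed hindlimb bones was enriched for CD117 (the product of Kit) on magnetic beads, stained and sorted, and cells were separated and lysed on a Fluidigm C1 chip. Complementary DNA was made with a SMARTer kit, libraries with Nextera XT, and sequencing was 150 bp paired-end in libraries of 96 cells, per the labels. The labels name 2 sort gates, GMP (in common usage the granulocyte-monocyte progenitor) and CD11b+ GMP-P, and each sample is 1 cell: 45 GMP cells and 47 CD11b+ GMP-P cells. The other abbreviations of gates and states are used as the labels and the annotation give them.

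Each gate carries 1 date code and its own range of cell numbers, and the labels name no animals. Each gate was therefore treated as 1 library, in the sense of 1 set of cells without a replicate, with cells not counted as replicates. The labels' libraries of 96 cells are a different use of the word. Whether cells of both gates were sequenced together in such a library is not given in the sources used here. Gate, animal, capture run and date cannot be told apart. No test between the gates was made, no p-value was computed, and differences describe these 2 libraries. The SD given beside a mean is the spread of cells within a group and measures no error between animals. There were 0 wild type cells among the samples, so the effect of the mutation was not analysed here.

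The deposited expression table gives log2 values for 23956 gene symbols in 92 cells. Back on the linear scale the values are TPM plus 1: without the Ly6g row, TPM summed to between 1000000 and 1000001 in every cell. Ly6g, the last row, was added outside that total, and with it the highest total was 1002695. Per the submitters' processing notes, Bowtie2 and RSEM were used with the mm9 build; versions and settings are not given in the sources used here. The second deposited file is the authors' assignment of each cell to 1 of 9 named states, as a state number and a name; how it was made is not given in the sources used here. The 2 files held 0 columns of other samples, 0 repeated gene names and 0 pairs of identical cells.

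TPM keeps no read depth, so the depth of each cell is unknown and the number of genes with a value above 0 stands in for it. Of all values 80.9% were 0, and the lowest TPM above 0 was 0.01. No cell was removed and no doublet caller was run; doublets are weighed in the closing section. The reference annotation at hand is of a later build than mm9, so it was used only for symbols, of which 22661 of the 23956 matched, and no coordinates are printed.

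For each gene the mean of log2(TPM + 1) over the cells of each gate was taken, and the difference was CD11b+ GMP-P minus GMP. This scale, with its pseudocount of 1, understates the change of low genes. Genes detected (TPM above 0) in at least 25% of the cells of at least 1 gate were compared. A size rule of 1 on the log2 scale (2-fold) described how many genes lay apart. Shares of cells carry exact Clopper-Pearson 95% intervals, which cover counting error only, and for a share of 0 the limit is 3 cells of the total.

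The named genes of the gate comparison were the 12 with the highest and the 12 with the lowest difference among genes detected in at least 50% of the cells of the higher gate, up to 4 members of each gene list with the largest absolute difference, and Gfi1, Irf8, Itgam, Kit and Cd34. For each state within a gate, and for Gran-1 between the gates, they were the 5 highest and 5 lowest by the same rule; a few of the genes so named are not reported here. A state was set against the other cells of its gate where it had at least 5 cells. There were 24 gene lists: neutrophil primary granule, neutrophil secondary and late granule, granulocyte transcription factor, monocyte, dendritic cell, stem and multipotent progenitor, megakaryocyte, erythroid, basophil and mast cell, eosinophil, B cell, T and NK cell, DNA replication (S phase), mitosis (G2/M phase), ribosomal protein, ribosome biogenesis, interferon response, immediate early and stress, ER chaperone and secretory protein folding, known Gfi1 target, sort gate, housekeeping, integrin with adhesion and chemotaxis, and cytokine receptor. Some genes stand in more than 1 list, among them Irf8, Elane, Kit and Cd34.

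A list was summarised by the median difference of its assessed members, where there were at least 3, and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 10 bins. The percentile describes these libraries and is not a test. Groups, lists, the rule for named genes, the size rule and all alternatives not said to be added later were chosen before the data were examined; the minimum of 3 members was set afterwards.

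The comparison was tested on simulated data made from the GMP and CD11b+ GMP-P values, with 7511 genes compared. Of genes shifted by 2 on the log2 scale, 49 of 50 shifted up and 48 of 50 shifted down passed the size rule. Of genes shifted by 1, 24 of 50 and 23 of 50 did. Of 7311 unshifted genes 455 (6.22%) passed it. Values of a gene were shuffled over the cells of both gates, so differences between the gates add to the spread behind that rate. The median of a list shifted by 2 lay at percentile 100. Of 200 unshifted lists, 13 fell outside the central 95% of random lists. Shuffling gene by gene also breaks the link between genes that vary together across cells. The count of 13 therefore does not show how often lists of such linked genes would fall outside. The recovery of shifted genes and lists describes these simulated shifts only.

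Alternatives tried were pseudocounts of 0.1 and 10, a 10% filter and no filter, the log2 ratio of mean TPM, equal medians of widely detected genes, cells matched between gates on genes detected, odd- and even-numbered cells, a marker-based assignment of states, and detection thresholds of 1 and 10 TPM. Those added after seeing the data left out the Myelo states, rescaled each cell without the genes of the granule lists, counted a gene as detected above 1 TPM, left out the 10% of cells with the fewest genes, or compared Gran-1 cells alone. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.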

Results

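Transcriptomes of 92 single bone marrow cells from Gfi1-R412X homozygous mice were examined, 45 from the GMP gate and 47 from the CD11b+ GMP-P gate. The study's title places the question in the states that cells pass through as they become granulocytes. A GMP cell had a median of 5611 genes detected (range 2775 to 6612) and a CD11b+ GMP-P cell 4143 (range 1993 to 5743). Genes of the 2 granule lists took a median of 7.63% of all TPM in GMP cells and 28.7% in CD11b+ GMP-P cells. Each gate is 1 library with no replicate, so no difference between the gates has a replicate check, and ± SD below is the spread of cells.

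The 2 gates held different cell states in the authors' annotation. In GMP, 24 of 45 cells were named Mono (53.3%, exact 95% interval 37.9 to 68.3) and 3 cMoP, which together made 60% (44.3 to 74.3). In CD11b+ GMP-P, Mono and cMoP made 1 of 47 cells (2.13%, 0.0539 to 11.3). The granulocyte states Gran-1 and Gran-2 made 8 GMP cells (17.8%, 8 to 32.1) and 24 CD11b+ GMP-P cells (51.1%, 36.1 to 65.9). Myelo-1, Myelo-2 and Myelo-4 held 21 CD11b+ GMP-P cells (44.7%, 30.2 to 59.9), of which 15 were Myelo-2, and 0 of 45 GMP cells, which allows a share of up to 6.67%. Multi-Lin was given to 5 GMP cells and 1 CD11b+ GMP-P cell, and MP to 5 GMP cells and 0 CD11b+ GMP-P cells. The sort itself sets these shares, and the intervals cover counting error only.

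**Figure D1:**
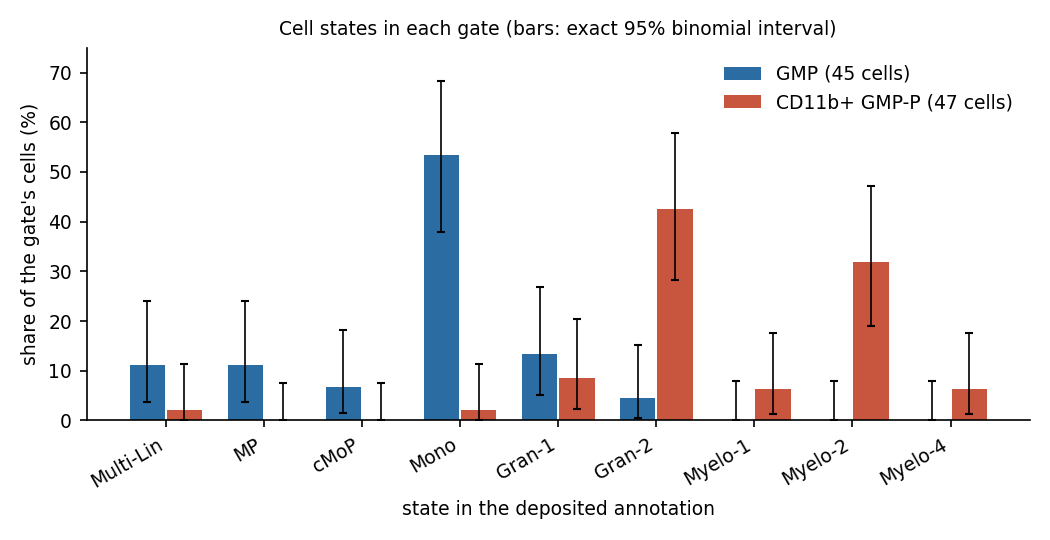
Share of each gate's cells (%) in each state of the deposited annotation, for 45 GMP cells and 47 CD11b+ GMP-P cells; black bars are exact 95% binomial intervals. Mono led in GMP with 53.3%, and Gran-2 (42.6%) and Myelo-2 (31.9%) led in CD11b+ GMP-P.

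CD11b+ GMP-P cells carried far more transcript of the late neutrophil granule and cytosol than GMP cells. S100a9 and S100a8, which encode the subunits of calprotectin, averaged 15.89 ± 2.13 and 15.99 ± 1.93 on the log2(TPM + 1) scale in CD11b+ GMP-P, against 5.72 ± 3.06 and 7.14 ± 3.51 in GMP, differences of 10.17 and 8.84. The 12 highest genes also held Chil3, a chitinase-like protein (9.97), Camp, the cathelicidin (8.97), Lcn2, a siderophore-binding protein (7.85), Ngp, a granule protein (7.10), and Ltf, lactoferrin (4.61); without the Myelo states Ngp was at 2.67 and Ltf at 0.14. The others of the 12 were 1100001G20Rik (6.96), Fcnb, a ficolin (6.77), Cd177 (5.60), Clec4a2 (5.08) and Lrg1 (4.48). Of 17 assessed members of the neutrophil secondary and late granule list, 15 were at least 2-fold higher, 1 was at least 2-fold lower and the median difference was 3.11, above all 10000 random lists. Ly6g, a member of that list, sits outside the TPM scaling. Most of the 12 highest genes were above 0 in most GMP cells too; S100a8 had a median of 38.4 TPM there, and the levels of a few TPM in GMP cells are weighed in the closing section.

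The primary granule genes, which neutrophils switch on earlier, went both ways. Mpo, myeloperoxidase, averaged 13.86 ± 1.67 in GMP and 9.68 ± 5.77 in CD11b+ GMP-P (difference -4.17), Ctsg, cathepsin G, differed by -4.75 and Elane, neutrophil elastase, by -2.87. Fcnb and Lyz2, lysozyme, were higher by 6.77 and 4.19; reads of Lyz2 can be shared with its paralog. Of 15 assessed members, 8 were at least 2-fold lower and 4 at least 2-fold higher, with a median of -2.10 at percentile 8.34. That median turned to 0.75 in cells matched on genes detected and to 0.94 without the Myelo states, where Mpo (0.23) and Elane (0.95) turned too. Elane had a median of 36043 TPM in the 20 Gran-2 cells of CD11b+ GMP-P and 4 TPM in the 15 Myelo-2 cells.

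Genes of monocytes and of ribosome building were lower in CD11b+ GMP-P, and so were those of early progenitors, though not beyond the median of all genes in every setting. Of 13 assessed monocyte genes 9 were at least 2-fold lower and 0 higher, with a median of -1.99 at percentile 0.01. Ly86, a partner of a Toll-like receptor homolog, differed by -4.62, Ms4a6c by -4.40, Irf8, a transcription factor of the monocyte and dendritic lineages, by -3.39, and F13a1, a subunit of coagulation factor XIII, by -3.01. Among stem and multipotent progenitor genes 8 of 13 were at least 2-fold lower (median -1.27, percentile 0.43), including Cd34 (-5.32), Gpr56 (-2.64), Cd27 (-1.82) and Meis1 (-1.45); relative to the median of all genes compared that list stood at -0.53, and at 0.0079 in even-numbered cells. Among ribosome biogenesis genes 16 of 17 were (median -2.97, below all 10000 random lists), with Nop58 at -4.18, Nop56 at -3.99, Gnl3 at -3.96 and Dkc1 at -3.91. All 49 ribosomal protein genes were at least 2-fold lower (median -2.21, percentile 0.06), among them Rpl3 (-3.37), Rps2 (-3.28), Rpl12 (-3.06) and Rpl10a (-2.87); their reads can be shared with pseudogenes, and without the Myelo states that median was -0.57. The 12 lowest genes were Snhg3 (-5.74), Cd34, Slc25a4 (-5.00), Hspe1 (-4.93), Cd48 (-4.79), Ctsg, Hmgn1 (-4.67), Ly86, Apex1 (-4.62), Cct3 (-4.57), Fkbp11 (-4.56) and Pa2g4 (-4.51).

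Cell cycle lists parted. The mitosis list had a median of 0.46, above all 10000 random lists, while 22 of its 28 members lay within 2-fold; Top2a differed by 1.71 and Mki67 by 1.16, against -1.61 for Cdc20 and -1.23 for Ccnb1, which were both above 0 in cells matched on genes detected, as was Ccnb1 by mean TPM. The DNA replication list had 15 of 24 members at least 2-fold lower and a median of -1.37 at percentile 36.9, with Mcm2 at -2.75, Mcm6 at -2.74, Mcm4 at -2.73 and Mcm3 at -2.42. In matched cells that median was -0.17.

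Genes of the secretory pathway were also lower in CD11b+ GMP-P, while those of the early stress response were lower within the range of random lists. In the ER chaperone and secretory protein folding list 15 of 17 members were at least 2-fold lower, with a median of -2.22 at percentile 1.28 that moved to -0.57 in matched cells. Calr, calreticulin, differed by -3.43, Pdia6 by -3.40, Atf4 by -2.66 and Hspa5 by -2.59. In the immediate early and stress list 12 of 15 were (median -1.59, percentile 7.47), with Egr1 at -2.65, Zfp36 at -2.53, Ier3 at -2.08 and Btg2 at -2.07. In the dendritic cell list 4 of 6 were lower (median -1.47, percentile 1.34, -0.16 in matched cells), H2-DMa by -3.07, while Id2 was higher by 3.06. Among housekeeping genes 9 of 12 were at least 2-fold lower (median -1.26, percentile 75.5), with Eef1a1 at -2.09, Sdha at -2.49 and Hprt at -1.72; in matched cells the median was -0.14 and Hprt was at 0.23.

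The first 5 medians given next lay close to 0 and changed sign in cells matched on genes detected, with equal medians of widely detected genes, or in both. The granulocyte transcription factor list had a median of -0.45 (percentile 95.8), with Ets1 at 2.94 and Cebpe, which drives late granule genes, at 2.53, against -1.92 for Myb, a progenitor factor. The sort gate list had a median of -0.26 (percentile 99.4), and Itgam, the gene for CD11b, was 3.44 higher. The integrin, adhesion and chemotaxis list had a median of -0.41 (percentile 97.6), with Itgb2 at 3.57 and Vcam1 at 2.46 against -2.55 for Itgb1. The cytokine receptor list stood at -0.38 (percentile 96.7), with Ifngr1 at -2.21 and Csf1r at -2.13. The interferon response list (4 members assessed) stood at -0.41 (percentile 78), with Xaf1 at -0.98. The basophil and mast cell list (3 assessed) had a median of -2.08 at percentile 13.2, which became 0.15 without the Myelo states. Markers of other lineages were scarce: 0 of 17 erythroid and 0 of 9 eosinophil genes in the table were detected often enough to compare, and 1 member each of the megakaryocyte (Fli1, -0.12), B cell (Cd79b, -1.58) and T and NK cell (Lck, 0.34) lists was.

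**Figure D2:**
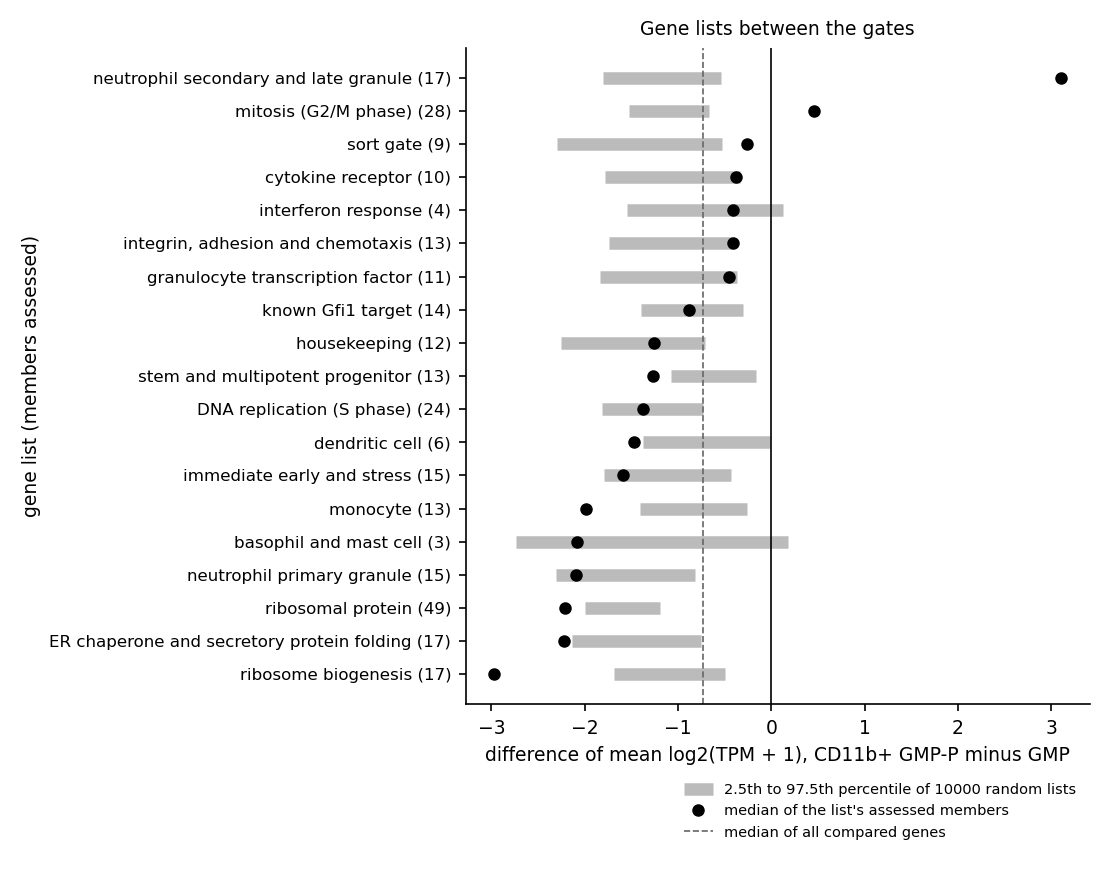
Median difference of mean log2(TPM + 1), CD11b+ GMP-P minus GMP, for the 19 gene lists with at least 3 members assessed (black points), with the central 95% of 10000 random lists matched on size and mean expression (grey) and the median of all compared genes (dashed, -0.74). The late granule (3.11) and mitosis (0.46) lists lie above their grey ranges, as do the sort gate and integrin lists, whose medians changed sign with equal medians of widely detected genes, while the ribosome biogenesis (-2.97), ribosomal protein, ER chaperone, monocyte, dendritic cell and stem and multipotent progenitor lists lie below.

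Of 7803 genes compared, 212 had a mean at least 2-fold higher in CD11b+ GMP-P and 3044 a mean at least 2-fold higher in GMP, and the median of all was -0.74. In the simulation 6.22% of unshifted genes passed the same rule in either direction. The simulation mixed values over both gates and had no common shift of all genes. That rate therefore does not settle how many of the 212 genes lie beyond the spread of cells. At least 8-fold apart were 34 genes higher in CD11b+ GMP-P and 219 higher in GMP. The 2-fold counts describe 2 libraries of unequal genes per cell. In 24 cells of each gate matched on genes detected they were 859 and 1175, 42.2% higher in CD11b+ GMP-P against 6.51% over all cells, with a median of -0.10. Matching left out most Myelo-2 (1993 to 3257 genes) and Myelo-4 cells (2148 to 2319), since few GMP cells had so few genes. It therefore changed the mix of states too, and its shifts cannot be put down to genes per cell alone. The share higher in CD11b+ GMP-P was 19.9% with equal medians of widely detected genes, 21.9% for mean TPM and 22.4% without the Myelo states. The median of all genes was -0.47, -0.52 and -0.31 in these 3 settings. Relative to the median of all genes compared, the late granule list stood at 3.84, mitosis at 1.2, monocyte at -1.25 and ribosome biogenesis at -2.24, and each kept that sign in all 13 alternatives. Absolute sizes depended on the setting: late granule genes ranged from 2.10 to 5.58, monocyte genes from -3.22 to -0.90 and stem and multipotent progenitor genes from -2.13 to -0.44 over all settings.

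Gfi1 itself, the mutated gene, was detected in 34 of 45 GMP cells (75.6%, exact 95% interval 60.5 to 87.1) and 36 of 47 CD11b+ GMP-P cells (76.6%, 62 to 87.7), with means of 3.78 ± 3.17 and 4.44 ± 3.43. Its transcript level does not check the genotype, since a stop codon need not change it. Gfi1 averaged 3.98 ± 3.32 in GMP Mono, 6.10 ± 2.35 in GMP Gran-1, 5.89 ± 2.84 in CD11b+ GMP-P Gran-2 and 2.57 ± 3.41 in Myelo-2. Of 14 assessed known Gfi1 targets 7 were at least 2-fold lower in CD11b+ GMP-P, 2 (Id2 and Ets1) were at least 2-fold higher, and the median of -0.89 sat at percentile 40.1 and was -0.18 in matched cells. Irf8, which GFI1 is known to repress, was detected in 66.7% of GMP cells (51 to 80) and 8.51% of CD11b+ GMP-P cells (2.37 to 20.4). Kit averaged 2.13 ± 2.24 in GMP and 1.96 ± 2.69 in CD11b+ GMP-P, and its difference of -0.17 changed sign among the alternatives (-0.77 to 1.05). It was above 0 in 75.6% of GMP cells (60.5 to 87.1) and 48.9% of CD11b+ GMP-P cells (34.1 to 63.9). That gap was smaller at stricter thresholds: 23 of 45 and 19 of 47 cells held Kit above 1 TPM, and 13 and 11 above 10 TPM.

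**Figure D3:**
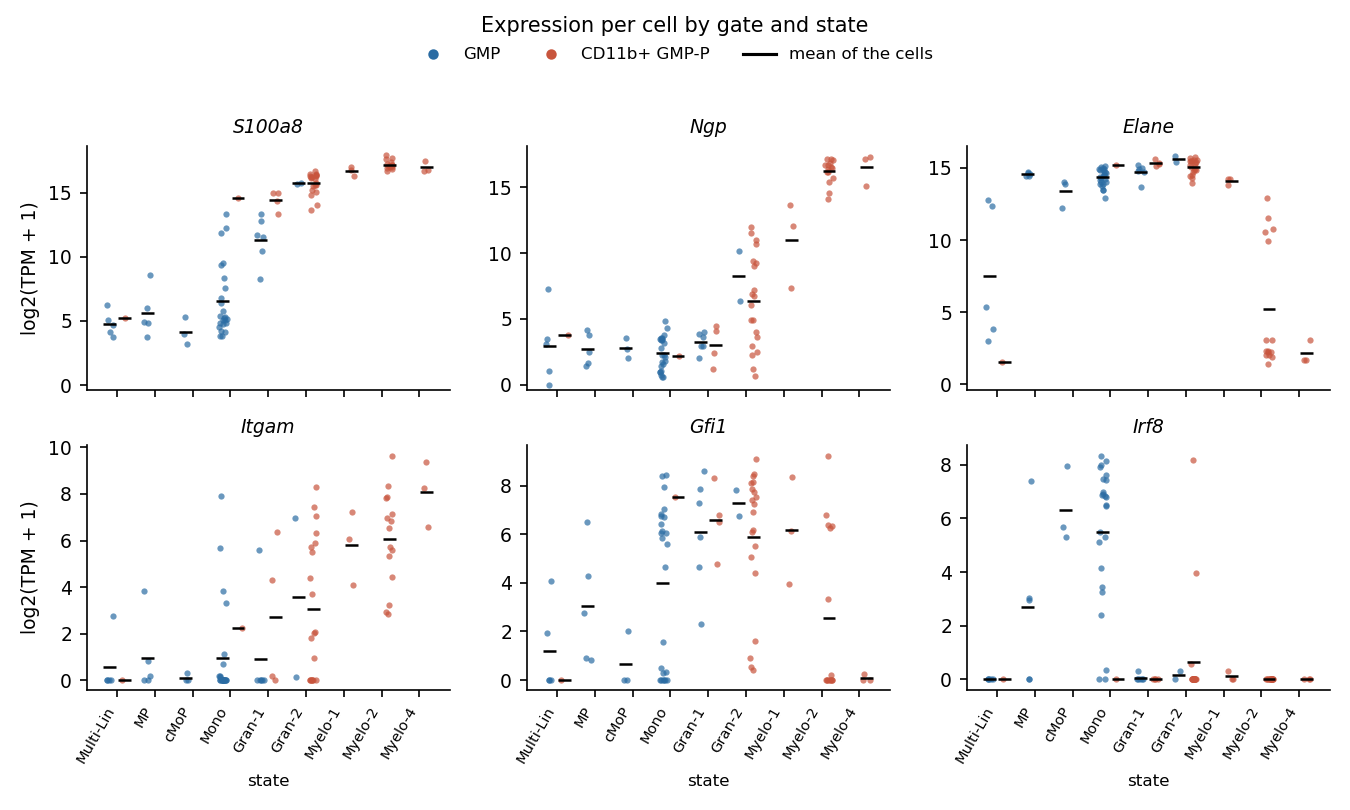
Expression per cell, log2(TPM + 1), of 6 genes by state (horizontal axis) and gate (colour); each point is 1 cell and black lines are means. Ngp averaged 16.19 and Elane 5.23 in the 15 Myelo-2 cells, against 6.34 and 15.07 in the 20 CD11b+ GMP-P Gran-2 cells.

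Gfi1 and Irf8, markers of opposite granulocyte and monocyte programmes, were often found in the same cell of the GMP gate. Both were above 0 in 22 of 45 GMP cells (48.9%, 33.7 to 64.2) and 4 of 47 CD11b+ GMP-P cells (8.51%, 2.37 to 20.4). Above 1 TPM the counts were 16 (35.6%, 21.9 to 51.2) and 1 (2.13%, 0.0539 to 11.3). Among the 24 GMP Mono cells, 12 held both above 1 TPM (50%, 29.1 to 70.9), 9 held Irf8 alone and 3 Gfi1 alone; a count of 13.1 would follow if the genes were independent there. All 6 GMP Gran-1 cells held Gfi1 above 1 TPM and 0 held Irf8, and 3 of 5 MP cells held both. Depth per cell is unknown, so a 0 for either gene can be a transcript that was missed.

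**Figure D4:**
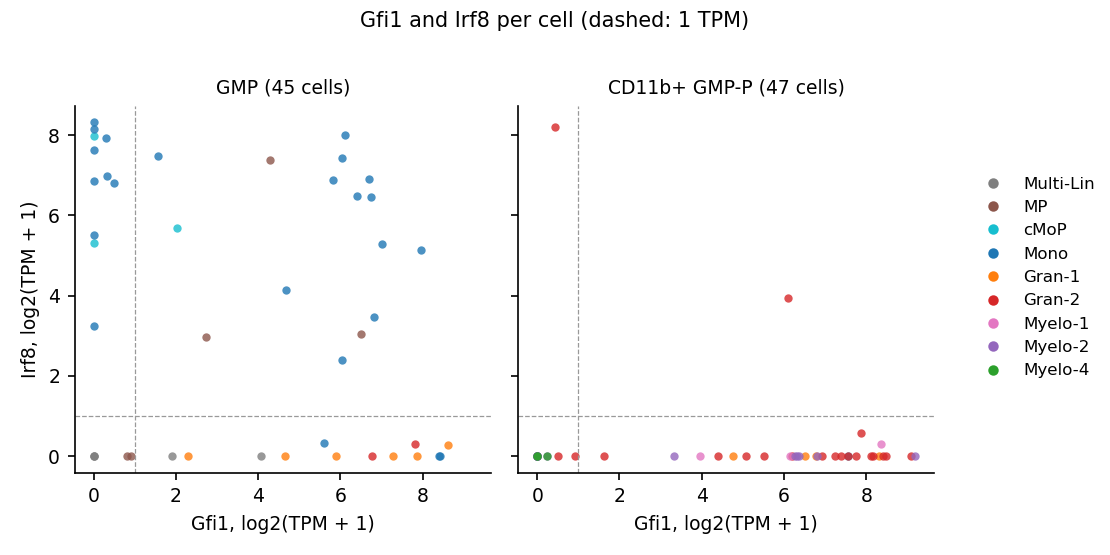
Irf8 against Gfi1, both as log2(TPM + 1), in each GMP cell (left) and CD11b+ GMP-P cell (right), coloured by state; dashed lines mark 1 TPM and cells at 0 for both overlap. Cells above both lines number 16 in GMP and 1 in CD11b+ GMP-P.

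Within the GMP gate, the 5 Multi-Lin cells were on average higher in some basophil and mast cell genes and lower in primary granule and monocyte ones. Cpa3, the mast cell carboxypeptidase, averaged 9.84 ± 1.88 against 0.24 ± 0.97 in the other 40 GMP cells, and Ms4a2, a chain of the high-affinity IgE receptor, 6.29 ± 5.77 against 0.40 ± 1.62. Ifitm1, Vamp5 and Rab37 made up the 5 highest genes. Of 7 assessed basophil and mast cell genes, 6 were at least 2-fold higher (median 2.89, above all 10000 random lists). Of 15 stem and multipotent progenitor genes 5 were at least 2-fold lower and 7 at least 2-fold higher (median 0.60, percentile 99.8). Only 2 of 17 erythroid and 2 of 12 megakaryocyte genes were assessed, of which 2 and 1 were at least 2-fold higher. Among 5 cells, a rare gene passes the detection filter if only a few of them hold it, which favours genes higher there. These counts therefore cannot show whether either list was higher. The lowest genes were Ly6c2 (-9.37), Kars (-7.34), Clec12a (-7.16), Slpi (-6.96) and Elane (-6.94), and the primary granule list had a median of -3.60, below all random lists. The 5 cells were not alike. Elane was at 7.1 to 41.1 TPM in cells 14, 17 and 23 but at 7110 and 5287 TPM in cells 26 and 35, where Ms4a2 was at 0. The immediate early and stress list had 11 of 16 members at least 2-fold higher (median 2.03), and the DNA replication list 22 of 24 lower (median -2.39). Multi-Lin cells had a median of 3634 genes detected against 5611 over the gate. Of 8218 genes compared, 3526 were at least 2-fold lower in them and 767 at least 2-fold higher, with a median of -0.78.

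The 24 Mono cells were highest in Ly86 (4.20), F13a1 (3.94), Irf8 (3.92), Fdps (3.90), an enzyme of sterol synthesis, and Ass1 (3.89), and 10 of 15 monocyte genes were at least 2-fold higher than in the other 21 GMP cells (median 1.54, above all 10000 random lists). Their lowest genes were Casp4, Ifi27, Rnf125, Vamp5 and S100a9 (-2.80 to -2.49). The 6 Gran-1 cells were high in S100a8 (4.84), Mrgpra2b, Sirt2 and Arsb, and low in Ly86 (-5.23), Lyz2 (-4.57), Rps27 and Akr1b3; the monocyte list stood at -1.29 and the primary granule list at 1.06. The 5 MP cells were highest in 2210013O21Rik, Tmem216 (5.22), Lpcat3, Med10 and Rnmtl1 (4.53) and lowest in Ier3, Vrk3, Thoc6, Fars2 and Klf4 (-4.07 to -3.26), and 0 of 15 immediate early genes were at least 2-fold higher there (median -0.94). How the annotation was made is not given, and where it used these genes their order describes the names and is no independent finding.

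In the CD11b+ GMP-P gate, Gran-2 and Myelo-2 cells were opposite in their granule genes. The 20 Gran-2 cells were highest in Mpo (7.52), Elane (7.47), Ctsg (7.24), Srgn (7.14) and Gstm1 (6.52) and lowest in Ltf (-7.79), Ngp (-6.38), Mmp8 (-5.65), Cd177 (-4.85) and Ifitm6 (-4.76) relative to the other 27 cells. The 15 Myelo-2 cells were highest in Ltf (10.35), Ngp (9.08), Mmp8, a collagenase (7.09), Camp (6.16) and Ifitm6 (5.84) and lowest in Mpo (-10.02), Srgn (-9.72), Ctsg (-9.01), Elane (-8.15) and Prtn3, proteinase 3 (-7.42). In Myelo-2 cells all 49 ribosomal protein genes, all 15 assessed ribosome biogenesis genes and all 18 ER chaperone genes were at least 2-fold lower, while the mitosis list stood at 0.22, above all 10000 random lists. Many other genes were lower there too: of 7077 compared, 3367 were at least 2-fold lower and 184 at least 2-fold higher. The median of all was -0.93, against -2.86, -2.09 and -3.12 for those 3 lists. Myelo-2 cells had a median of 2936 genes detected, and granule list genes took a median of 57% of their TPM, which lowers the share left for every other gene.

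No state had 5 cells in both gates. Gran-1, compared after seeing the data with 4 CD11b+ GMP-P and 6 GMP cells, showed Fcnb at 11 ± 0.64 against 3.27 ± 2.45 and Chil3 at 9.48 ± 3.80 against 2.86 ± 2.26, with Ube2g2, Dynlt1b and Pnpla7 next. The lowest were Nmd3, Aaas, Ifi47, Klf6 and Fkbp11 (-6.25 to -5.23). Within Gran-1 the late granule list had 5 of 17 members at least 2-fold higher and a median of 0.20, the primary granule list a median of 0.50 and the monocyte list -0.58, and the ribosomal protein list stood at -0.21. The immediate early and stress list had 9 of 13 members at least 2-fold lower there (median -1.22, percentile 1.31), and the ribosome biogenesis list had 6 of 17 (median -0.80, percentile 1.99). Between so few cells chance differences are large: 2169 of 9201 genes were at least 2-fold higher and 2022 at least 2-fold lower.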

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

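Among small groups of cells (1 state in 1 gate, 4 to 6 cells), 42 sets of values were checked for a lone cell far from the rest, and 7 were found. Chance gives about 1 in 20 for values that vary smoothly, but where a gene is at 0 in all other cells any cell with a transcript stands apart, which holds for 3 of the 7, so that rate does not apply to them. Of the GMP Gran-1 cells, cell 25 had 2775 genes detected where the next had 5296, and the same cell had the lowest Elane, 13.68 on the log2(TPM + 1) scale, with the next at 14.74. Cell 12 of that state had Itgam at 5.60 and the other 5 cells at 0. Cell 40 had Irf8 at 0.29 and the others at 0, a level under 1 TPM. Among the MP cells of the GMP gate, cell 30 had Itgam at 3.83 with the next at 0.85. Among the Multi-Lin cells of the GMP gate, cell 14 had Itgam at 2.78 with the others at 0, and cell 17 had a granule list share of 1.02% of TPM with the next at 2.61%. All 7 lay in the GMP gate, which held 3 of the 4 groups checked, and 3 were high values of Itgam, whose protein separates the gates.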

How the results depend on the processing

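Settings added after seeing the data were those without the Myelo states, rescaled without granule list genes, with detection above 1 TPM, and without the 10% of cells with the fewest genes. Most results moved in size more than in direction. Of 90 named genes of the gate comparison 75 kept their sign in all 13 alternatives, and so did 62 of 65 with a difference of at least 2. Of 247 list medians over the alternatives 224 kept the reported sign and 168 also stayed within 1.5-fold of it, and 11 of 19 lists kept their sign throughout. Of 1170 values of named genes 1138 kept the sign and 694 also stayed within 1.5-fold. Of 60 state gene values recomputed with a pseudocount of 10, 5 stayed within 1.5-fold and 55 moved, with 0 changes of sign. Late granule (2.10 to 5.58), mitosis (0.10 to 1.52), monocyte (-3.22 to -0.90) and ribosome biogenesis medians (-4.06 to -1.62) kept their signs throughout. Leaving out a replicate was impossible with 1 library per gate, and the planned comparisons within states of at least 5 cells in both gates, or with states weighted equally, had no such state. Unknown depth limits every share of cells with a gene. Changes of filter act through the members assessed, and unless the setting itself changes the genes or cells, the cause was not tested.

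With a pseudocount of 0.1, 344 genes were at least 2-fold higher in CD11b+ GMP-P and 4595 in GMP, and medians were 4.26 for late granule, -3.22 monocyte, -2.40 dendritic, -2.13 stem, -3.21 basophil and mast cell, -2.30 DNA replication, -4.06 ribosome biogenesis, -2.18 immediate early and -1.57 known Gfi1 target genes. With a pseudocount of 10 the counts were 98 and 1247, and medians 2.41 for late granule, -0.93 monocyte, -0.64 dendritic, -0.52 stem, -1.03 basophil and mast cell, -0.70 DNA replication, -1.62 ribosome biogenesis, -0.90 immediate early and -1.34 ER chaperone genes. A filter at 10% of cells gave -0.998 for basophil and mast cell and 0.12 for interferon genes. No filter gave -0.90 for monocyte, 0.00 dendritic, -0.44 stem and -0.54 basophil and mast cell genes.

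As the log2 ratio of mean TPM, 661 genes were higher in CD11b+ GMP-P, and medians were -0.0319 for primary granule, 5.58 late granule, -0.68 basophil and mast cell, -0.71 DNA replication, -1.10 ribosomal protein, -2.18 ribosome biogenesis, 0.14 interferon, -0.83 ER chaperone and -0.56 housekeeping genes; Ccnb1 turned to 0.0669. With equal medians of widely detected genes, 555 were higher, and medians were -1.10 for primary granule, 4.26 late granule, 0.65 granulocyte transcription factor, -1.08 ribosomal protein, -0.92 immediate early, -1.16 ER chaperone, 0.34 sort gate, -0.10 housekeeping, 0.50 integrin and 0.0342 cytokine receptor genes.

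In cells matched on genes detected (24 of each gate) the counts were 859 and 1175. The matching left out most Myelo-2 and Myelo-4 cells, so it changed the mix of states as well as genes per cell. Medians were 0.75 for primary granule, 2.10 late granule, 0.18 granulocyte transcription factor, -0.16 dendritic, -0.17 DNA replication, 1.52 mitosis, -1.08 ribosomal protein, -1.73 ribosome biogenesis, 0.0203 interferon, -0.57 ER chaperone, -0.18 known Gfi1 target, 1.07 sort gate, -0.14 housekeeping and 0.46 integrin genes. Per3 turned to 1.005, Cdc20 to 0.0198, Ccnb1 to 0.51, Elane to 0.75, Fcgr3 to 0.0714, Hprt to 0.23 and Pgk1 to 0.0634. Odd-numbered cells gave 319 higher genes and medians of 4.59 for late granule, 0.0656 interferon and 0.0352 sort gate genes. Even-numbered cells gave 323 higher genes and medians of -2.69 for basophil and mast cell and 0.21 for integrin genes.

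Without the Myelo states (26 CD11b+ GMP-P cells left) the counts were 408 and 1410, and medians were 0.94 for primary granule, 2.21 late granule, 0.24 granulocyte transcription factor, 0.15 basophil and mast cell, -0.47 DNA replication, -0.57 ribosomal protein, -1.88 ribosome biogenesis, 0.17 interferon, -0.47 ER chaperone, 0.56 sort gate and -0.32 housekeeping genes. Mpo turned to 0.23, Per3 to 0.61, Srgn to 0.15, Elane to 0.95, Fcgr3 to 0.0303 and Hprt to 0.44, which the 21 cells left out account for. The 3 Myelo-1 cells did not share the low Elane and Mpo of the other Myelo cells, with means of 14.07 and 13.20. Rescaled without granule list genes, 326 genes were higher and the integrin median was 0.0601. With detection above 1 TPM the late granule median was 3.86. Without the 10% of cells with the fewest genes, medians were -0.82 for primary granule, -1.41 ribosomal protein, 0.30 interferon and -1.58 ER chaperone genes.

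When cells were assigned to states by their marker scores, 31.1% of GMP cells scored highest for stem and multipotent genes against 11.1% named Multi-Lin. At 10 TPM, Gfi1 and Irf8 were both found in 22.2% of GMP cells, 37.5% of GMP Mono cells and 2.13% of CD11b+ GMP-P cells, and at 1 TPM in 2.13% of the last.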

Other observations

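Tests chosen only after the result was seen were those of the late granule genes without Anxa1, all of those of the basophil and mast cell genes, and those of Gfi1 levels in Mono cells. Along the CD11b+ GMP-P states, some genes outside the granules were highest in the Myelo cells. Itgam averaged 3.06 ± 2.99 in 20 Gran-2, 5.8 ± 1.58 in 3 Myelo-1, 6.09 ± 2.04 in 15 Myelo-2 and 8.06 ± 1.39 in 3 Myelo-4 cells. Id2, an inhibitor of helix-loop-helix factors and a known Gfi1 target, averaged 4.05 ± 3.55, 8.34 ± 0.61, 6.31 ± 3.81 and 8.40 ± 0.79 in the same states, while Gfi1 averaged 5.89 ± 2.84, 6.15 ± 2.20, 2.57 ± 3.41 and 0.08 ± 0.14. Cebpe averaged 5.88 ± 2.15, 6.39 ± 1.82, 5.06 ± 2.71 and 4.10 ± 0.74. In the 3 cMoP cells of the GMP gate, Irf8 averaged 6.32 ± 1.44 and Csf1r, the receptor of macrophage colony-stimulating factor, 6.16 ± 2.69, against 5.49 ± 2.63 and 3.29 ± 2.89 in Mono cells.

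Late granule transcripts stood a little above 0 in GMP cells of other states: over the 37 named Mono, cMoP, MP or Multi-Lin, the median was 4.71 TPM for Camp, 4.65 for Ngp, 2.46 for Chil3 and 0.50 for Ltf. If reads were carried over from the CD11b+ GMP-P cells, each gene should stand at 1 small fraction of its CD11b+ GMP-P mean. Over 8 genes with a mean of at least 1000 TPM the highest fraction was 1005 times the lowest, but this came from Anxa1, with a median of 997 TPM in those GMP cells. Over the other 7 genes the spread was 2.79-fold, from 1.31 to 3.66 per 10000, so carried-over reads may account for these levels, and a few TPM of such genes cannot be read as expression. Expression that starts in the granulocyte states was tested too: 6 of the 8 genes had a Gran-1 median at least 2 times that of Mono, too few to decide for the set, although S100a8 (3123 against 37.7 TPM) stands far above such a fraction.

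Some basophil and mast cell transcripts stood out in the cells named Multi-Lin, but not alike: Cpa3 was at 116 to 4017 TPM in all 6, and Prss34 at 5721 and 3986 TPM in 2 cells and under 1 TPM in the other 4. Other members of the list did not stand out: Gzmb, Tpsb2 and Cma1 were at 0 in all 6. Hdc was above 10 TPM in 70 of the other 86 cells, and Mcpt8 in 15. Reads carried over from other cells, at the highest fraction found above for late granule genes, would give at most 366 TPM. Of the 6 cells 5 held Cpa3 above that, while 0 of the other 86 cells passed 29.2 TPM. That fraction is a median over 37 cells, and a single cell can lie higher. Ngp, with a median of 4.65 TPM in those cells, was at 7.26 on the log2(TPM + 1) scale in Multi-Lin cell 23. The 366 TPM is therefore no limit for a single cell, and carried-over reads were not excluded. Doublets with another GMP cell giving 25% of the RNA would hold Elane, Mpo, Prtn3 and Plac8, each above 1000 TPM in all 40 other GMP cells, at no less than 25.2% of the lowest of these in all but 1 gene; in cells 14, 17 and 23 the second lowest gene was at 10.4% or less, which argues against them there. In cells 26 and 35 it was at 108% or more. Clec12a, at least 57.9 TPM in each of the other 40 GMP cells, was at 1.38% and 0.88% of that level there. The lowest share of any such gene in those 40 cells, at 25% of the RNA, was 2.94%. This goes against a doublet but rests on 1 of the genes tested. Outside the test, Ly6c2 was at 1.68 and 155 TPM in cells 26 and 35. It was detected in all 40 other GMP cells, with a mean of 12.38 ± 1.60 on the log2(TPM + 1) scale. Ly6c2 was named as the lowest gene of the Multi-Lin cells, which include both, so doublets stay open for cells 26 and 35. Other forms of the test, tried first, could not decide either. Multi-Lin cell 56 of the CD11b+ GMP-P gate was not tested for doublets. No biological explanation was tested, and the annotation holds no basophil or mast cell state.

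Gfi1 and Irf8 in the same Mono cells was the third pattern. Doublets with a Gran-1 or Gran-2 cell would bring S100a8, yet 3 of the 24 GMP Mono cells held at least 50% of the Gran-1 median (3123 TPM), against 12 cells with both genes. The cut is not strict, as S100a8 ran from 8.25 to 13.30 on the log2(TPM + 1) scale in GMP Gran-1 cells, and a doublet with a low one could miss it. Cells 28 and 47, with both genes and S100a8 at 13.31 and 12.22, passed it, so such doublets stay open for these. Reads carried over from other cells would leave Gfi1 near a few per 10000 of the highest level, but its Mono median of 51.7 TPM was 8.84% of that level (585 TPM). Doublets with an MP cell at equal shares would bring at most 45 TPM of Gfi1, judged from only 5 MP cells, and 10 of the 12 cells with both genes held more, 5 of them more than the highest MP cell itself (90.1 TPM), which argues against such doublets as the cause of the whole pattern. Doublets of a Mono cell with Gfi1 alone and another with Irf8 alone were not tested and stay open. Mono cells 1 and 33, for example, had Gfi1 at 8.42 and 8.40 on the log2(TPM + 1) scale and Irf8 at 0. That both genes may be transcribed in 1 cell is a hypothesis that was not tested. With no wild type cells, whether the mutation plays a part was not analysed here.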
